A study of Homo sapiens with 3 samples.

How the data were processed

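The series holds 3 Affymetrix arrays of MCF-10A cells after 16 days in three-dimensional culture, with 1 array each for parental cells, cells with an empty vector and cells expressing 14-3-3ζ. Groups were taken from the sample titles and source names. Per the labels, total RNA was extracted with Trizol and biotin-labelled by the standard Affymetrix protocol.

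The authors deposited an intensity per probe set on a linear scale, headed Signal, and per the submitters' processing notes these values were made with MAS5. The software version and the scaling target are not given in the sources used here. The 2% trimmed mean of the signals was 130 for 14-3-3ζ, 167 for vector and 179 for parental cells, so the arrays had no common mean over all probe sets. Per the file headers, the vector and 14-3-3ζ arrays also carry detection calls (Present, Marginal, Absent), a signal log ratio on the log2 scale with low and high bounds, change calls, and a detection p-value and change p-value per probe set. Per the labels these comparisons were made against the parental array. Over the probe sets Present on each array, log2 ratios of the deposited signals to parental differed from the signal log ratio by a median of 0.0011 for 14-3-3ζ and -0.0013 for vector. Single probe sets can differ more: the Pearson r of these 2 values was 0.975 for 14-3-3ζ and 0.8345 for vector. The parental signal was taken from the deposited value table of the series; its columns for the other arrays equalled their array files on all 54675 probe sets. Detection calls of the parental array were not used here, so Present and Absent refer to the vector and 14-3-3ζ arrays only, also where vector and parental are compared. The deposited p-values compare probe pairs within 1 array or between 2 arrays, and none is printed.

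Probe sets were named from the platform annotation: 41091 had 1 gene symbol, 1801 several and 11721 none, and 62 were controls. Symbols were compared through gene identifiers with RefSeq genes of assembly GRCh38.p14; 41037 probe sets matched and 0 symbols were updated. That table served also to place genes on chromosomes, and no coordinates are printed. Only probe sets with 1 symbol stood for a gene, and the one with the highest mean log2 signal over the 3 arrays was used, which gave 19775 genes. A gene was measured when its probe set was Present on the vector or the 14-3-3ζ array (11663 genes). Signals below 0.1 were set to 0.1 before log2. A gene counted as 2-fold when the log2 difference was at least 1 in size, and against both controls when this held for each control in the same direction. With 1 array per group there are no residual degrees of freedom, so no test was run and no p-value computed.

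The 34 gene lists hold 791 genes, of which 718 had a probe set and 605 were measured. Each list's median difference was placed among the medians of 10000 random lists of the same size, drawn from 50 bins of mean log2 signal, and the percentile describes these arrays only. For a gene not Present on the dimmer array the fold is given as a lower bound from the deposited signals. It is the brighter signal over the higher of the dim signal and the lowest Present signal of that array (5 for 14-3-3ζ, 6.1 for vector). No error of the signals enters this bound. The median signal of Absent probe sets was 7.6 for 14-3-3ζ and 9.4 for vector.

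Named genes followed a rule: all probe sets of YWHAZ; among genes Present on both arrays with calls, the 12 farthest above and the 12 farthest below the nearer control; the 4 brightest genes Present on 14-3-3ζ and Absent on vector, and 4 of the reverse; for vector against parental the 5 highest and 5 lowest; and for each list up to 4 members Present on both arrays with the largest difference from vector. Other members of the 14-3-3 family and of the lists were named in addition, chosen after their values were seen, among them members with bounds and members near 0.

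The groups, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined. The alternatives were the median signal over all probe sets of a gene on each array, centring of each array on its median, quantile normalization, no filter on detection calls, Present on all arrays with calls, low signals raised to the median Absent signal, probe sets ending in _x_at or _s_at left out, the authors' signal log ratio, thresholds of 1.5-fold and 3-fold, and the parental array or the mean of both controls as the control. Centring used each array's median over the probe sets Present on both arrays with calls. The median of the differences of a gene's probe sets Present on vector or 14-3-3ζ, each set against itself on the other array, was added after seeing the data. On simulated data, with a scaling error added to the 14-3-3ζ array, counting was tested against both controls and the list step against vector. Of 200 among 11663 genes given a log2 change of 2, 95.5% were recovered, and 212 other genes (1.85%) were called, or 159 with arrays centred on the median of all 11663 genes. Fewer genes were changed than differed in the data, and smaller changes were not simulated. A list with planted changes came out at percentile 100 and one without at 67.3.

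Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.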

Results

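Total RNA from MCF-10A cells was hybridised to Affymetrix expression arrays after 16 days in three-dimensional culture. MCF-10A is an established, non-tumorigenic human mammary epithelial line, and in such culture its cells grow as rounded, polarised clusters. The 3 arrays held unmodified parental cells, cells stably carrying an empty vector, and cells stably expressing 14-3-3ζ, an adaptor protein that binds phosphorylated partners and is encoded by YWHAZ. Each group had 1 array, so no difference has a replicate check and no p-value is given; the number of arrays limits the precision of every value. The vector and parental arrays, both without added YWHAZ, gave the background against which the 14-3-3ζ array was read. The question, from the series title, was which genes differ when 14-3-3ζ is overexpressed.

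The array of 54675 probe sets had a median signal of 26.5 for 14-3-3ζ cells, 31.1 for vector cells and 31.3 for parental cells. In the authors' detection calls, 24494 probe sets (44.8%) were Present on the 14-3-3ζ array and 24202 (44.3%) on the vector array. Of 19775 genes with a probe set, 11663 were called Present on at least 1 of these arrays and form the measured genes below. Each gene's value, fold or bound is that of its brightest probe set and holds for that probe set only. Across them, the median difference between 14-3-3ζ and vector was -0.31 on the log2 scale. Lists of genes were therefore set against random lists of equally bright genes, which carry the same shift. The spiked-in hybridisation controls had a mean log2 signal of 9.99, 10.14 and 10.30 on the 14-3-3ζ, vector and parental arrays.

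YWHAZ was read by 5 probe sets, which went in opposite directions. Probe set 200641_s_at gave a signal of 8416.7 in 14-3-3ζ cells, against 3332.4 in vector cells and 3480 in parental cells, a difference of 1.34 on the log2 scale (2.53-fold) from vector. In the authors' deposited table its signal log ratio against parental was 1.6, with bounds of 1.3 and 1.9. The other YWHAZ probe sets were all lower in 14-3-3ζ cells than in vector cells, by -0.90 for 200640_at, -0.87 for 200639_s_at, -0.58 for 200638_s_at and -0.58 for the dim 214848_at. The median of the 5 differences was -0.58, so the direction depends on which probe set stands for the gene.

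Among the other 14-3-3 genes, SFN (14-3-3σ, a p53 target made by squamous and mammary epithelium) stood apart. Its signal was 1323.2 in 14-3-3ζ cells, 14475.3 in vector cells and 15039.1 in parental cells, a difference of -3.45 from vector, and its other probe sets gave -3.99 and -4.77. YWHAH differed by -0.89, YWHAB by -0.64, YWHAG by -0.41, YWHAE by -0.33 and YWHAQ by 0.04. Once the shift of -0.31 is set aside, YWHAG and the brighter YWHAE probe set lay close to the median of all genes. The other YWHAE probe set gave -0.93, and a dimmer YWHAH probe set gave 0.51. The family as a whole (7 genes measured) had a median of -0.41 against -0.25 for matched random lists, at percentile 25.4 of them.

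In 14-3-3ζ cells, many squamous and cell junction genes that were among the brightest in both controls had far lower signals, and vimentin, decorin and other mesenchymal genes had far higher ones. Not all bright genes did so on their brightest probe set: PERP (16136.4 in vector cells) differed by only -1.42 there, but another of its probe sets gave -4.30. Among genes Present on both arrays with calls, the farthest below both controls were LCE3D, a late cornified envelope protein (signal 39.3 in 14-3-3ζ cells, 10654.9 in vector cells), and ABCG1, a cholesterol efflux transporter, which was 147-fold lower than in vector cells. IL1RN, the interleukin-1 receptor antagonist, was 120-fold lower, FLG (filaggrin) 118-fold, the gap junction gene GJB2 110-fold and EREG (epiregulin, an EGFR ligand) 101-fold lower. HSD17B2, CALML5, SPRR1B, ADGRG1, the desmosomal cadherin DSC3 and the tight junction gene CLDN1 completed the 12 lowest, between 98.1-fold and 74.9-fold below the nearer control. The 12 highest were led by MAP1B, a microtubule-associated protein (1976.7 against 21 in vector cells), PAPSS2, which makes the sulfate donor (2379.3 against 30.2), and SELENOP, a secreted selenium carrier (8777 against 153.9).

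PCDH9, CYP4B1, SULT1E1, PAPPA, SPX, VIM, MUC1, CCN2 and MAN1A1 made up the rest of the 12 highest, between 54.5-fold and 22.6-fold above the nearer control. VIM, the mesenchymal intermediate filament, had a signal of 9555.3 in 14-3-3ζ cells, 205.7 in vector cells and 354.9 in parental cells. MUC1, a luminal mucin, gave 7122.9, 236.8 and 276.3, and CCN2, a matricellular protein, 2118.1, 86.4 and 67.2. In the authors' deposited table each of these 12 genes carried an increase call against parental and each of the 12 lowest a decrease call. All Present probe sets of these 24 genes went the same way, but some gave much smaller differences from vector, down to 0.43 for PAPPA, 1.67 for SPX, 2.19 for VIM and 2.49 for SELENOP, and -2.09 for EREG. Among list members named below, KRT8, OASL, BOC and FOXO4 carried a no-change call although 2-fold apart from parental.

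Genes called Absent on the dimmer array have only a bound on their difference, taken against the higher of that array's own signal and its lowest Present signal. DCN (decorin) was at least 129-fold higher in 14-3-3ζ than in vector cells, SRGN (serglycin) at least 567-fold, MGP (matrix Gla protein) at least 143-fold and CNR1 (a cannabinoid receptor) at least 510-fold on the brightest probe set. Other probe sets gave log2 differences down to 3.59 for DCN, 3.85 for SRGN and 5.47 for CNR1. In the opposite direction, PI3 (elafin) was at least 541-fold lower, IVL (involucrin) at least 390-fold, SPRR2G at least 365-fold and SPRR2B at least 280-fold lower. These bounds refer to the deposited signals and are not lower limits on the authors' signal log ratio. Against parental, that ratio was smaller in size than the signals gave for PI3 (-7.7 against -9.16) and IVL (-7.6 against -8.85). It was also smaller for SRGN and SPRR2G, and larger for DCN, MGP, CNR1 and SPRR2B. DCN reached a signal of 13842.1 on the 14-3-3ζ array and PI3 12540.2 on the vector array.

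**Figure D1:**
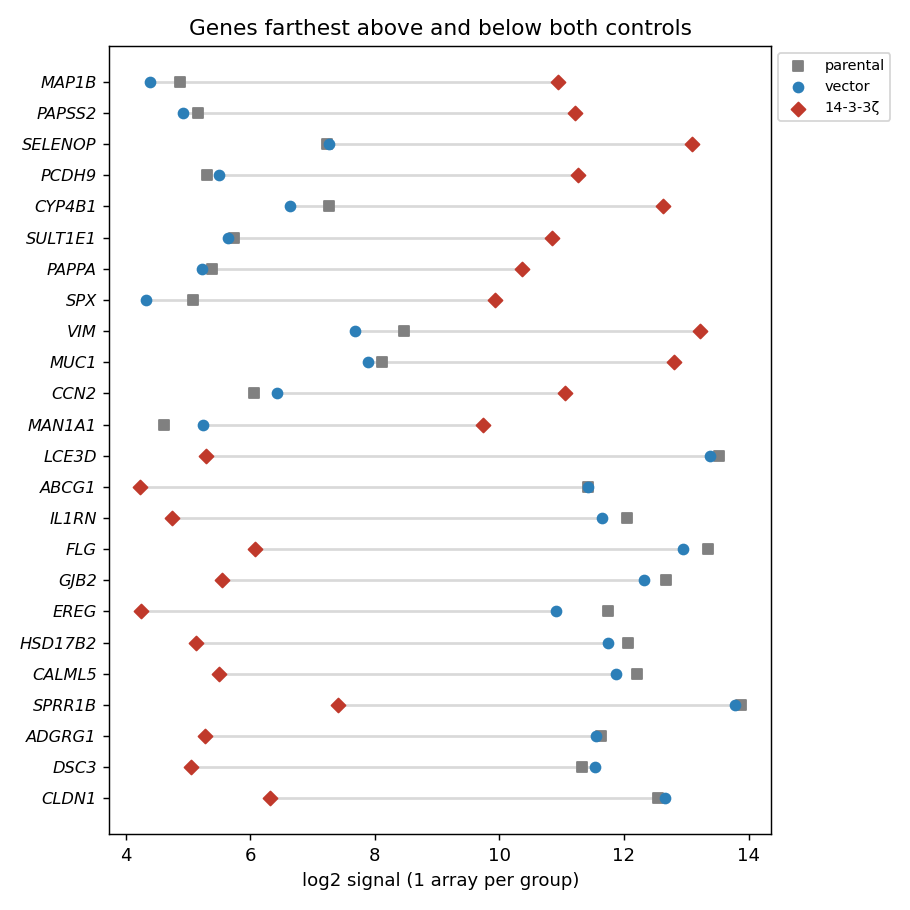
Log2 signal of the 24 genes farthest above and below both controls, with 1 point per array for parental (grey squares), vector (blue circles) and 14-3-3ζ cells (red diamonds). The controls lie close together for each gene, while 14-3-3ζ cells lie apart, by 6.56 above vector for MAP1B and by -8.08 for LCE3D.

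Counted over the 11663 measured genes, 3338 (28.6%) differed from both controls by at least 2-fold in the same direction, 964 of them higher and 2374 lower in 14-3-3ζ cells. Against vector alone there were 3858 genes (1254 higher, 2604 lower) and against parental alone 4033 (1189 higher, 2844 lower). Part of this imbalance goes with the shift of the whole array. With each array centred on its median over probe sets Present on both arrays with calls, 1465 genes were higher and 1654 lower than both controls. Among the 9306 genes Present on both arrays with calls, 2112 passed (544 higher, 1568 lower). Where a 2-fold gene had several Present probe sets, all of them went the same way in 1617 of 1782 genes (90.7%).

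**Figure D2:**
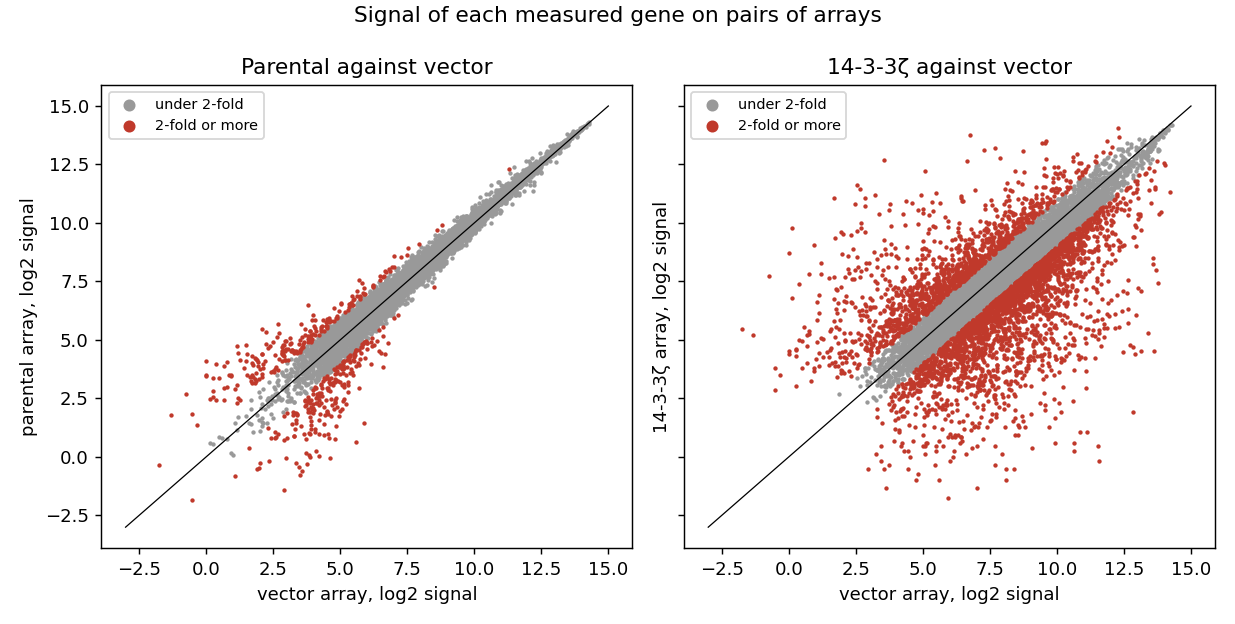
Log2 signal of the 11663 measured genes, parental against vector on the left and 14-3-3ζ against vector on the right, with 1 point per gene. Genes that differ by 2-fold or more are red, 445 in the left panel and 3858 in the right, and the line marks equal signal.

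Genes of epithelial adhesion were lower in 14-3-3ζ cells almost throughout: 22 of 25 measured genes were at least 2-fold below vector and 0 above. The list's median was -4.20, against -0.35 for matched random lists, below all 10000 of them (percentile 0). CDH1 (E-cadherin) had a signal of 94.9 against 3814.9 in vector and 4361 in parental cells, a difference of -5.33. CLDN1 differed by -6.34, the desmosomal cadherins DSC2 and DSG3 by -5.78 and -5.08, and the splicing regulator ESRP1 was at least 60.8-fold lower. TJP1 (-0.32) and CLDN7 (-0.21) lay near the shift of all genes, but CLDN7 gave -0.86 against parental.

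Mesenchymal genes were higher, with 11 of 22 at least 2-fold above vector and 3 below, and a median of 1.48 against -0.30 in matched random lists (percentile 100). Beside VIM (5.54), the transcription factor ZEB1 differed by 4.57, FN1 (fibronectin) by 3.91 and TAGLN (transgelin) by 3.77. On the brightest probe set CDH2 (N-cadherin) was at least 33.3-fold higher, while another gave 1.24 on the log2 scale. SPARC was at least 65.7-fold and ZEB2 at least 12-fold higher. Other members did not share this: SNAI2 differed by -0.13, COL1A1 by -3.09, MMP2 by -1.54 and POSTN by -1.33. The short list of fibroblast markers, which shares DCN, COL1A1 and POSTN with this one, went both ways, with FBLN1 4.46 higher (0.24 on another probe set), FAP at least 67.8-fold lower, 2 of 6 genes 2-fold higher, 4 lower and a median of -2.21 against -0.35 (percentile 0.29). With no filter on detection calls, the median of the fibroblast list lay 0.044 above matched random lists, and against parental it was -2.97.

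Squamous differentiation genes made up the list with the lowest median, -5.94 against -0.33 (percentile 0), with 25 of 28 genes at least 2-fold lower and 0 higher. FLG (-6.88), CALML5 (-6.37), SPRR1B (-6.36) and the suprabasal keratin KRT1 (-6.05) were Present on both arrays, while 14 members were not Present on the dimmer array. KRT1 gave 136.4 in 14-3-3ζ cells, 9024.5 in vector cells and 9038.6 in parental cells. With such genes at their bound the median was the same, but a bound departs from the measured difference only below the lowest Present signal. This cannot show how far the median rests on genes that were not detected.

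Basal and luminal markers were mixed. Of 15 basal markers, 3 were 2-fold higher and 7 lower (median -0.70 against -0.26, percentile 1.66), with DST at -3.42, LAMB3 at -2.63, ITGA6 at -2.30 and MME at 2.97; the median difference over the Present probe sets of DST was 1.09. The basal keratins stayed abundant, KRT5 at 8955.8 in 14-3-3ζ and 14512 in vector cells (-0.70), KRT14 at -1.55 and KRT15 at 0.81. Of 13 luminal markers, 3 were higher and 5 lower (median -0.16 against -0.31, percentile 73), with MUC1 (4.91) and KRT8 (2.79) opposed to ERBB3 (-4.86) and CD24 (-3.41).

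Proliferation genes were lower as a group. In the cell cycle list 25 of 28 genes were 2-fold below vector and 0 above (median -1.82 against -0.26, percentile 0), among them CCNB1 (-2.72), DLGAP5 (-2.47), CCNB2 (-2.46) and TPX2 (-2.43). In the DNA replication list 16 of 23 were lower and 0 higher (median -1.55 against -0.32, percentile 0), with RRM2 at -2.89, TYMS at -2.60, CCNE2 at -2.04 and CDC6 at -1.99. CCNB1 gave a signal of 75.8 against 499.1 in vector and 498 in parental cells. Between the controls, the vector minus parental median was 0.08 for the cell cycle list (percentile 99.2).

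Genes of EGFR and ERBB ligands and feedback were lower in 15 of 26 cases and higher in 1 (median -1.26 against -0.34, percentile 0). The ligands EREG (-6.66) and TGFA (-5.64) led, HBEGF was at least 77.2-fold lower, ERBB3 differed by -4.86 and the early response gene IER3 by -3.43. In the Notch list 9 of 16 genes were lower and 1 higher (median -1.95 against -0.34, percentile 0), with the ligands JAG1 (-3.24) and JAG2 (-2.98), DTX4 (-2.80) and HES2 (-2.55). Against parental the Notch median was smaller, -1.29, with 8 genes lower and 2 higher, and vector minus parental gave 0.10 (percentile 99.7). Wnt genes split, 2 higher and 7 lower of 15 (median -0.88 against -0.34, percentile 3.15). Among secreted inhibitors, DKK1 (4.32) and DKK3 (2.40, and 0.23 on another probe set) were higher and SFRP1 (-4.92) was lower. The receptor FZD6 (-1.27) was lower too. Of 7 hedgehog genes, 2 were higher and 2 lower (median -0.01 against -0.24, percentile 69.2), with GAS1 at 3.92, CDON at 3.02, BOC at -1.17 and GLI3 at -0.85; without probe sets ending in _x_at or _s_at, GAS1 gave -3.44.

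In the TGF-beta response list 5 of 23 genes were higher and 9 lower (median -0.44 against -0.30, percentile 26.1). TAGLN and the latent TGF-beta binding gene LTBP3 (2.47) were higher, PMEPA1 (-2.32) and TGFBI (-2.20) lower, and INHBA was at least 85.7-fold lower on its brightest probe set, with -2.16 on another. Of 23 YAP and TAZ targets, 6 were higher and 6 lower, and the median of 0.11 lay above that of matched random lists, -0.38 (percentile 99.4). CCN2 (4.62) and CCN1 (2.85), the best known of these targets, were higher, while AJUBA (-3.23) and AMOTL1 (-3.16) were lower. In the PI3K and FOXO list 4 of 21 were higher and 2 lower (median -0.14 against -0.36, percentile 89.4), with FOXO1 at 2.15, PIK3R1 at 1.23, CITED2 at 1.17 (0.74 against parental) and FOXO4 at -1.74. Against parental the list's median was -0.01, at percentile 99.1.

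Of 26 p53 targets, 4 were higher and 5 lower (median -0.30 against -0.37, percentile 67.3), with SFN and GDF15 (-3.24) lower and TP53I3 (2.21) and GADD45B (1.88) higher. CDKN1A, the cell cycle inhibitor p21, differed by -0.11. Of 19 apoptosis regulators, 1 was higher and 5 lower (median -0.30 against -0.34, percentile 56.8). The death ligand TNFSF10 differed by -4.83, PMAIP1 by -2.67, the survival gene BCL2L1 by -1.85 and BID by -1.74, whereas BMF, a pro-death BH3-only gene, was at least 17.2-fold higher.

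Basement membrane and integrin genes were close to random lists as a group, 2 of 24 higher and 10 lower (median -0.34 against -0.33, percentile 47.1). ITGA2, the collagen-binding integrin chain, differed by -5.23, LAMB3 by -2.63, ITGA6 by -2.30 and NID1 by -1.80 (-0.87 against parental). Matrix proteases and their inhibitors were lower in 17 of 23 cases and higher in 3 (median -1.44 against -0.30, percentile 0), but only 1 gene was 2-fold higher against parental. CTSV (-5.14), MMP9 (-2.72, and -1.45 against parental) and the urokinase receptor PLAUR (-2.57) were lower and the inhibitor TIMP1 (1.77) was higher.

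Interferon response genes were higher in 10 of 20 cases and lower in 5 (median 1.07 against -0.17, percentile 100). Of the 20 genes, 12 were not Present on the dimmer array. Among members Present on both arrays, 4 were named for the largest differences, and of these only ISG15 was higher. IFI44L was at least 132-fold higher than in vector cells, IFI44 at least 35.9-fold (2.05 on another probe set), IFI6 at least 33.7-fold and IFIT1 at least 20-fold, and ISG15 differed by 1.22 (0.84 against parental). Other members of the response were lower: OAS1 by at least 20.3-fold, OAS3 by at least 18-fold, OASL (-1.78), TAP1 (-1.39) and IFIH1 (-1.04, and -0.93 against parental). Genes of NF-kB and cytokines were lower in 11 of 18 cases and higher in 1 (median -1.44 against -0.31, percentile 0.01), with CXCL2 (-2.04), NFKB2 (-1.59) and CXCL8 (-1.29) lower. This list also separated the controls, with a vector minus parental median of -0.37 (percentile 0.01).

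Hypoxia response genes were lower in 11 of 24 cases and higher in 1 (median -0.97 against -0.37, percentile 0.15). VEGFA differed by -3.47, EGLN3 by -2.85 and CA12 by -2.70, and LOX, a collagen cross-linking enzyme, by 3.16. In the glycolysis list 4 of 20 genes were lower and 0 higher (median -0.10 against -0.28, percentile 93): HK2 (-3.16), PFKP (-2.51), PFKFB3 (-2.46) and the glucose transporter SLC2A1 (-2.20), while LDHA differed by -0.06. No gene of oxidative phosphorylation differed by 2-fold (0 of 26), yet their median of 0.02 lay above matched random lists (-0.33, percentile 99.7), with UQCRB at 0.73, NDUFB5 at 0.58, COX5B at 0.46 and ATP5F1C at -0.57.

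Of 18 cholesterol synthesis genes, 8 were lower and 1 higher (median -0.93 against -0.37, percentile 0.51), with SC5D (-2.54), SQLE (-2.27), MSMO1 (-1.72) and DHCR7 (-1.71). Of 15 fatty acid synthesis genes, 5 were lower and 2 higher (median -0.81 against -0.36, percentile 2.84), with FABP5 (-5.33) and SCD (-2.99) lower and LPIN1 (3.18) and ELOVL5 (2.07, and 0.30 on another probe set) higher. Both lists also separated the controls, with vector minus parental medians of -0.31 (percentile 0) and -0.28 (percentile 0.01).

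The unfolded protein response list held 7 lower genes and 0 higher of 25 (median -0.65 against -0.37, percentile 6). The lower members included genes of amino acid synthesis and uptake, ASNS (-3.81), PSAT1 (-2.16) and SLC7A11 (-1.93), and the pseudokinase gene TRIB3 (-3.88), whereas the chaperone gene HSPA5 gave -0.47 and 0.20 on its probe sets. Of 15 heat shock genes, 6 were lower and 1 higher (median -0.68 against -0.32, percentile 3.70), with HSPB1 at -2.67, HSPH1 at -1.90, HSPA4 at -1.30 and DNAJB4 at 2.20; without probe sets ending in _x_at or _s_at, HSPA4 gave 0.60. Of 21 NRF2 response genes, 2 were higher and 3 lower, and the median of -0.01 lay above random lists (-0.35, percentile 98.7); the controls differed too, by a vector minus parental median of 0.08 (percentile 100). AKR1B10 (-5.34) and HMOX1 (-3.23) were lower and NQO1 (1.45) was higher. Ribosomal protein genes gave 0 of 21 at 2-fold (median -0.20 against -0.21, percentile 54.1), with RPL14 at -0.40 and RPL22 at -0.39.

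**Figure D3:**
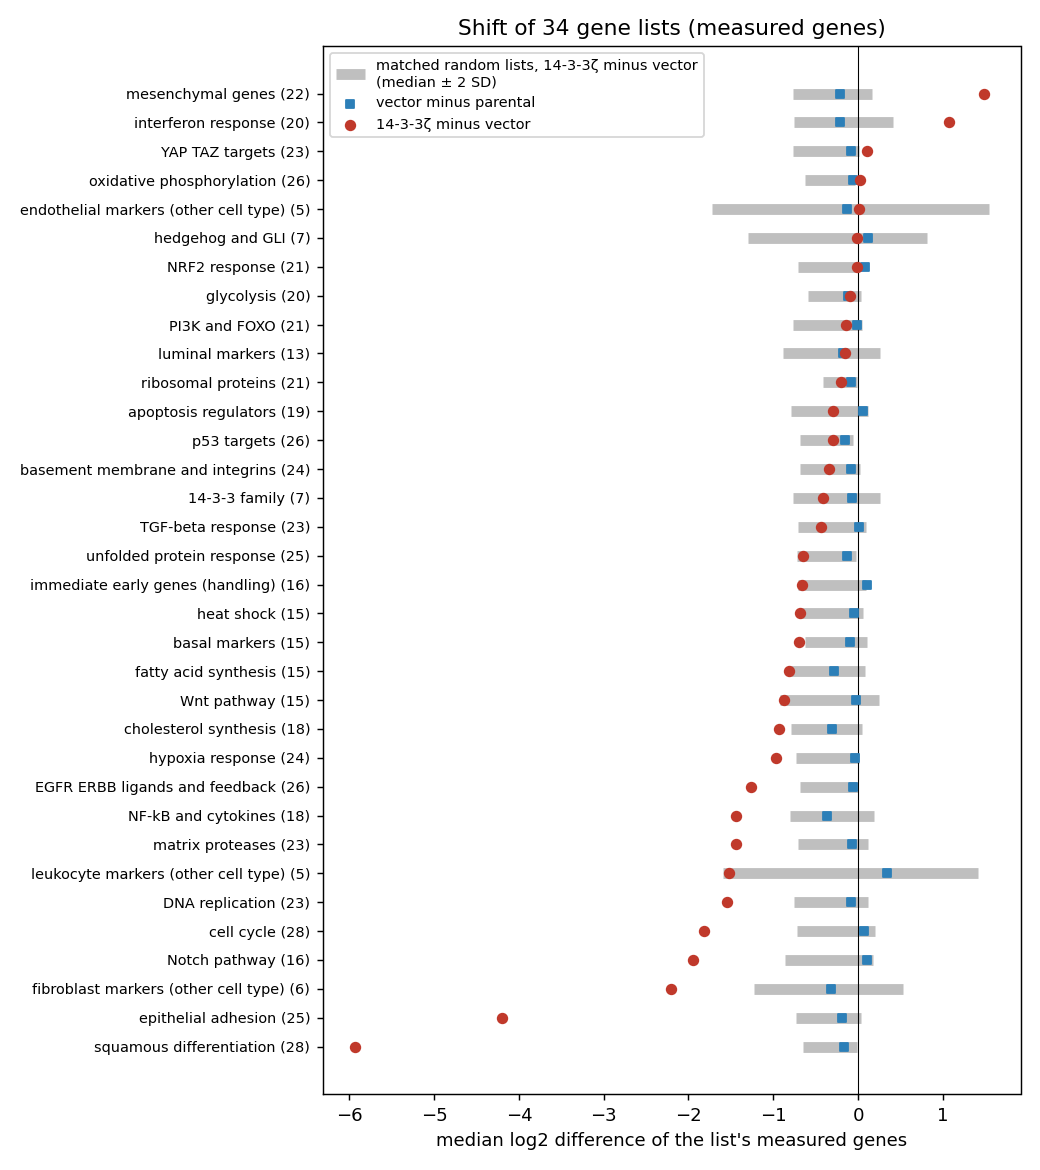
Median log2 difference of the measured genes of each of the 34 lists, with the number of genes in brackets, for 14-3-3ζ minus vector (red circles) and vector minus parental (blue squares); grey bars span 2 SD on either side of the median of matched random lists for 14-3-3ζ minus vector. Squamous differentiation (-5.94) and epithelial adhesion (-4.20) lie farthest below the bars, and mesenchymal genes (1.48) farthest above.

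Of the 34 lists, 17 had a 14-3-3ζ minus vector median outside the central range of random lists, between percentiles 2.5 and 97.5, with 5 above it and 12 below. If the genes of each list were independent draws, 1.7 lists would lie outside. Genes of a list can move together and some lists share genes, so 1.7 is no chance level for these lists. Vector minus parental, with no transgene, gave 12 lists outside (7 above, 5 below), with medians between -0.37 and 0.34 over all 34 lists. Besides the lists already named with a control difference, these were TGF-beta response (0.01), apoptosis regulators (0.05), PI3K and FOXO (-0.01) and immediate early genes (0.10) above the range, and epithelial adhesion (-0.19) and fibroblast markers (-0.32) below it.

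The counts and gene values of the lists are against vector. The number of genes 2-fold apart from both controls was the same or 1 fewer per list and direction, except for basement membrane and integrin genes, with 8 lower instead of 10, and matrix proteases, with 1 higher instead of 3. Against parental alone there were more 2-fold genes in some lists, such as 4 higher apoptosis regulators, 5 higher NRF2 genes, 8 lower p53 targets and 8 lower fatty acid synthesis genes. Other named members whose difference from parental was smaller by more than 1.5 times were VIM (4.75), CDH2 (4.18), ZEB1 (3.89), FN1 (3.21), DKK3 (1.45), IFI6 (5.26), IFI44 (3.47), KDR (4.90) and TNFSF10 (-4.20). It was larger by more than 1.5 times for LTBP3 (3.39), POSTN (-2.92), SQLE (-2.93), CXCL8 (-2.02), OASL (-2.37) and EREG (-7.48). Against parental, the deposited signals gave 4.31 for ZEB2 and 10.65 for IFI44L. Both genes have only a bound against vector and no parental call was used, so these values are not read as larger.

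Markers of other cell types and of sample handling were read on the same arrays. Of 5 leukocyte markers, 0 were higher and 3 lower (median -1.52 against -0.09, percentile 2.93), with CD14 at -0.55. Of 5 endothelial markers, 1 was higher and 2 lower (median 0.01 against -0.09, percentile 55.9): KDR, the VEGF receptor, was at least 67.2-fold higher, ROBO4 differed by -1.76 and PECAM1 by 0.08. On the dimmer array, 4 of the 5 leukocyte and 3 of the 5 endothelial markers were not Present, so both medians lean on undetected signals. Of 16 immediate early genes, which respond to handling, 1 was higher and 6 lower (median -0.66 against -0.31, percentile 4.60), with KLF4 at -3.70, IER3 at -3.43, MYC at -1.94 and JUN at -1.66. As a sign of RNA quality, the 3' to 5' signal ratio of GAPDH was 1.02 for 14-3-3ζ, 1.03 for vector and 1.07 for parental cells, and that of ACTB was 2.0, 1.54 and 1.5.

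Vector and parental cells were much alike. Among genes Present on both arrays with calls, the widest gaps in favour of vector were in dim genes, RFX4 (27.8 against 1.69), HTR2A (24.2 against 1.75), CFAP95-DT (31.1 against 3.39), CFI (16.7 against 2.10) and SYT6 (34.9 against 5.22). In the opposite direction, POSTN (periostin) was at 127.1 in vector and 384.3 in parental cells (-1.60), followed by PTGR2 (-1.55), PBLD (-1.54), ALG1 (-1.37) and ANXA2P3 (-1.24). POSTN is also in the mesenchymal list, and CFI, a complement regulator, was higher again in 14-3-3ζ cells, at 363.6.

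In all, 445 of the 11663 measured genes (3.82%) differed by 2-fold between vector and parental, 230 higher and 215 lower in vector cells, and the median difference was -0.09. Among the 9306 genes Present on both arrays with calls the number was 66. Across genes, which are not independent replicates, log2 signals correlated with a Pearson r of 0.977 between vector and parental and 0.737 between 14-3-3ζ and vector.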

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

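All alternatives below were planned except the median of probe set differences, which was chosen after seeing the data. With 1 array per group, a moved value has no replicate spread to be set against, and signal over background limits dim genes most. No paired analysis was possible because each group had 1 array.

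YWHAZ (1.34 for 14-3-3ζ minus vector) turned to -0.58 as the median of its probe sets' differences and to -0.90 without probe sets ending in _x_at or _s_at, since both settings replace the only probe set that was higher. It was 1.64 with centred arrays, 1.56 after quantile normalization and 1.7 with the authors' deposited table of signal log ratios. DST turned to 1.09 as the median of its probe sets' differences. Leaving out probe sets ending in _x_at or _s_at turned GAS1 to -3.44 and HSPA4 to 0.60, each then read by another probe set.

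The median signal over probe sets, taken on each array, can set different probe sets against each other, so its values show no reversal of a gene: YWHAZ -0.42, DST 0.60, IFIH1 0.66, HTR2A in vector minus parental -0.68, and 873 genes 2-fold apart between vector and parental. As the median of differences, IFIH1 was -1.04, HTR2A 3.79 and that count 572. The parental signal of HTR2A (1.75) lay below the lowest Present signals of the other arrays (5 and 6.1), so the size of its difference is uncertain.

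The counts moved with the filter and the threshold, as fewer or more genes enter. Against both controls (3338), there were 5600 genes with no filter on detection calls, 2112 Present on all arrays with calls, 5624 at 1.5-fold and 1865 at 3-fold. For 14-3-3ζ minus vector (3858), these settings gave 7742, 2406, 6413 and 2189. For vector minus parental (445), they gave 3571, 66, 1209 and 202, and raising low signals to the median Absent signal gave 293, where the cause was not tested. Apart from these and the 873 above, the settings left each count within 1.5 times. Centring moved the share of higher genes among those apart from both controls from 28.9% to 47.0%, and quantile normalization to 47.3%.

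The number of lists outside the random range (17) stayed between 15 and 19. Epithelial adhesion, squamous differentiation, cell cycle, DNA replication, EGFR and ERBB, Notch, matrix protease, hypoxia and cholesterol lists lay below it in 12 of 12 settings, the main one included, and mesenchymal and oxidative phosphorylation lists above it in 12 of 12. YAP and TAZ and interferon lists lay above it in 11 of 12 and the NRF2 list in 10. NF-kB lay below it in 10 of 12, basal markers in 9 of 12 and fibroblast markers in 9 of 10; with no filter on detection calls, fibroblast markers lay at 0.044 relative to random lists, as more members enter. Among the 156 named genes, 986 values stayed close, 9 values of genes at least 2-fold apart took the opposite sign and the rest moved; among the 34 lists, 319 stayed close, 49 moved and 1 took the opposite sign.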

Other observations

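The families by symbol root, and the tests on array scaling, RNA degradation and fibroblasts, were chosen only after the results were seen.

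Gene families grouped by symbol root (185 with at least 8 measured members) gave 4 below and 4 above all but the outermost 0.1% of matched random lists. Kallikrein genes (KLK, proteases of epithelial surfaces) had a median 14-3-3ζ minus vector difference of -4.51, with 8 of 9 at least 2-fold lower, SERPINB protease inhibitors -2.69 (6 of 8 lower; vector minus parental -0.41), PRSS serine proteases -2.77 (7 of 9) and TNFRSF receptors -1.56 (6 of 10). Clustered protocadherins (PCDHB) had a median of 1.47, with 8 of 13 genes higher and 0 lower, phosphodiesterases (PDE) 1.25 (6 of 11 higher, 1 lower) and HLA genes 0.85 (4 of 11 higher, 1 lower), while HLA genes had a vector minus parental median of -0.31. The 337 ZNF zinc finger genes had a median of 0.06 against -0.24 for random lists.

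The breadth of the difference was the first pattern: 3858 genes differed 2-fold between 14-3-3ζ and vector and 445 between vector and parental, a ratio of 8.67. Array scaling as the whole cause is argued against by a ratio that was still 7.99 with centred arrays, and RNA degradation would not give the 341 genes at least 4-fold higher on 14-3-3ζ than on both controls, against 77 for vector over parental. For the 996 genes at least 4-fold lower, the GAPDH ratio of 3' to 5' signal (1.02 against 1.03 and 1.07 on vector and parental) goes against degradation. The ACTB ratio (2.0 against 1.54 and 1.5) goes with it, and the 341 genes stayed under the bound of 500 set for excluding it. The 0 of 26 oxidative phosphorylation and 0 of 21 ribosomal protein genes at 2-fold cannot decide this. Degradation need not reach all transcripts alike, and these genes are not among the 996. A part from degradation is therefore left open. Cells of another line carrying CDKN2A and MTAP, a locus deleted in MCF-10A, would bring these genes, but 0 of their probe sets were both Present and at least 4-fold above both controls (a dim MTAP probe set was Present on vector too, at 64.7), and fibroblasts would bring type I and III collagen, of which 0 genes were Present and 2-fold higher. An effect of 14-3-3ζ, drift or selection while the stable line was made, and a line that lacks the locus too stay open as untested.

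YWHAZ probe sets in opposite directions were the second pattern. A candidate explanation is a transgene transcript that only 200641_s_at detects, for example because the other probe sets lie in parts of the mRNA the transgene lacks. That probe set lay 1.91 above the next highest of the gene, a gap as large in 5 of 809 other genes with at least 4 Present probe sets (0.618%), where the median gap was 0.22. Probe positions and the transgene sequence were not used here, and cross-hybridisation of this probe set was not tested.

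Genes of chromosomes 20 and 18 lay lower together on the 14-3-3ζ array, the third pattern. Relative to all genes, the 263 genes of chromosome 20 had a median of -0.394 and the 145 of chromosome 18 of -0.36, against random sets with an SD of 0.053 and 0.074. The other 20 autosomes lay between -0.15 and 0.10, but not all within the bulk of random sets: chromosome 19 (0.098) lay at percentile 99.85 and chromosome 22 (-0.149) at 1.35. On chromosome 20, 68.8% of genes lay below the overall median, and vector minus parental showed 0.02 and -0.0023 for chromosomes 20 and 18. Against parental the relative medians were -0.404 and -0.32. Loss of a copy in the 14-3-3ζ cells may account for this. The bounds of 0.3 and 0.4 were set beforehand for the difference from vector, and -0.394 lies between them while -0.404 lies just past; both are within 1 SD of 0.4, so loss cannot be told apart from a shared change in transcription. No copy number was measured here.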
